A study of Homo sapiens with 6 samples.

How the data were processed

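Total RNA was measured by Illumina sequencing in 6 cultures of A375, an established human melanoma cell line. Per the labels, 3 cultures were left untreated (control replicates 1 to 3) and 3 were treated for 24 h with hMGL (treated replicates 4 to 6), an engineered human enzyme that breaks down methionine. The labels describe the cultures as independent. No replicate number is shared between the groups, so no pairing or block was used. The labels do not say whether the libraries were made by poly(A) selection or by removal of ribosomal RNA.

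The deposited files hold a table of transcripts per library. Per the file headers, they give estimated counts (expected counts, not whole numbers and not scaled between libraries), TPM (abundance scaled by effective length within each library), and the length and effective length of each transcript in bases. The submitters' processing notes name kallisto 0.45.0 and DESeq2 1.30.0 without saying what each was used for, and the columns are those of a kallisto abundance table. The genome build and the release of the transcript index were not given in the sources used here. The effective length exceeded the length for 25.7% to 27.1% of the transcripts.

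Each table lists 244939 transcripts by Ensembl identifier without a version. Of these, 203436 were matched to GENCODE 29 (GRCh38) and their estimated counts were summed to genes. The other 41503 transcripts, which took 4.86% to 5.13% of the counts of a library, were not matched to a gene by their identifier. Among these are Y copies of pseudoautosomal transcripts, marked PAR_Y, because such records were removed from the annotation before matching. All 41503 were left out of the gene sums, so the level given for a gene with such transcripts is a part of its total. Gene positions are those of GENCODE 29, and gene symbols are current ones where a gene has been renamed.

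Total estimated counts per library were 59954677, 53441686 and 58161646 for control replicates 1, 2 and 3, and 53682075, 51918674 and 50760266 for treated replicates 4, 5 and 6. The transcript of RN7SL1, the RNA of the signal recognition particle, took 3.21% to 4.52% of the counts and 16.1% to 22.1% of the TPM of a library. Estimated counts carry both counting error and the error of sharing reads between transcripts, and the second was not measurable from these files. The common biological coefficient of variation between replicates was 0.074.

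The design, the gene lists, the rule for named genes and 20 alternatives were fixed before the data were examined, and 3 further alternatives were chosen after seeing the data. In the test over all genes, gene sums were rounded to whole numbers, genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), and libraries were scaled by the trimmed mean of M values (TMM). Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust, two-sided). P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are treated over control, CPM are counts divided by the TMM-scaled library size, and errors of CPM are standard deviations over 3 libraries. Adjusted p values of single genes come from this edgeR model unless another is named. TMM sets the typical gene to no change, so every fold change is relative to the other genes of the library and not to the amount of RNA per cell.

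The named genes were chosen by a rule in 3 parts. The first part took the 12 genes with the highest and the 12 with the lowest log2 fold change among genes past the threshold with a symbol, a mean of at least 10 CPM, and all 3 treated libraries on the same side of all 3 control libraries. The second part took, from each gene list, up to 3 members that rose and up to 3 that fell, those with the lowest adjusted p. The third part took genes fixed by name whatever their values, among them MAT2A, AHCY, MTR, CTH, CBS, ATF4, ASNS, DDIT3, CHAC1, TRIB3, SLC7A11, CDKN1A, MITF and SOX10. The text gives a part of the genes that the rule takes.

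The 35 gene lists were written from general knowledge. They cover the amino acid response driven by ATF4, methionine, serine, folate and polyamine metabolism, aminoacyl-tRNA synthetases, the endoplasmic reticulum, lipid synthesis, glutathione, the cell cycle, histones, p53 targets, the BCL2 family, melanocyte and dedifferentiated states, MAPK output, interferon, NF-kB, methylation and demethylation enzymes, ribosomes, lysosomes, glycolysis, mitochondrially encoded mRNAs, heat shock, metallothioneins, and markers of other cell types. Each list was compared with all other genes by camera (preset correlation between genes 0.01, limma 3.58.1), with Benjamini-Hochberg over the lists. Camera with the correlation estimated from the data and fry, which asks whether the members of a list move one way on balance without comparing them with other genes, were run beside it. For each list the members past the threshold were counted over all genes tested and, where this differs, adjusted over the list alone.

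The alternatives were DESeq2 size factors, library totals alone, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and a mean of 10 counts), DESeq2 1.42.0, limma-voom, an offset for the effective transcript length, unrounded counts, limma on log2 TPM with 1 or 0.1 added, a minimum fold change of 1.5, leaving out the mitochondrially encoded genes, and leaving out each replicate in turn. Those chosen after seeing the data were protein-coding genes alone, an offset per library for GC content and transcript length, and leaving out 114 genes of the 7SL, 7SK, RMRP and RPPH1 families. The computations used R 4.3.3, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

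The tests were run on simulated data with the depth of these libraries and their common spread for every gene. Far fewer genes were changed than in the real comparison. The changed genes were drawn from those with at least 1 CPM in controls, so the recovery does not cover genes at lower levels. The edgeR test recovered 88.1% of the genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold, and 6 of its 198 calls were genes that had not been changed. DESeq2 recovered 80.6% and limma-voom 85.1% of the genes changed 1.5-fold. Camera with the preset or the estimated correlation, and fry, each called 2 of 2 lists made up of 20 changed genes and 0 of 33 unchanged lists, in data with no correlation between genes. Pairs of replicates were also checked for duplicate libraries. Their counts differed by more than counting error alone gives, with a chi-square over its degrees of freedom of 4.11 to 11.11.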

Results

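The data describe gene expression in A375 melanoma cells, in 3 untreated control cultures and 3 cultures treated for 24 h with the methionine-degrading enzyme hMGL. Libraries held 50760266 to 59954677 estimated counts. Across the genes tested, log CPM correlated with a Pearson r of 0.99 between libraries of a group and of 0.940 to 0.943 between libraries of different groups (across genes, which are not independent replicates).

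The comparison asks which genes change when the cells are treated with hMGL. Treated cells had far more mRNA of the integrated stress response, a program that a shortage of amino acids, among other stresses, can start. PPP1R15A, which directs the removal of the phosphate from the translation factor eIF2 alpha, went from 121.7 ± 1.99 to 4586 ± 79.7 CPM (SD, n = 3 per group), 37.7-fold higher. GDF15, a secreted stress hormone, was 40.4-fold higher. mRNAs of DNA replication, cholesterol and fatty acid synthesis, cytosolic ribosomal proteins and heat shock proteins were lower in treated cells by camera with a preset correlation. None of these 5 lists passed with an estimated correlation: adjusted p = 0.267 with an estimated correlation for DNA replication, cholesterol and fatty acids, 0.389 for ribosomal proteins and 0.276 for heat shock. HSPA8, the constitutive HSP70 chaperone, fell from 5992 ± 202 to 459.6 ± 16.4 CPM, 13.0-fold lower.

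Of 22580 genes tested with edgeR, 15677 (69.4%) passed the threshold, with 7881 higher and 7796 lower in treated cells. At least 2-fold differences were found for 3295 of the genes that were higher and 2849 of those that were lower, and at least 8-fold differences for 346 and 108. Among the 15421 protein-coding genes tested, 12080 changed. For 16542 genes (73.3%) the 3 treated libraries lay on a single side of the 3 control libraries, where chance gives 10%. The median log2 fold change of all genes was −0.015. When a change of at least 1.5-fold was required, 7987 genes passed, 4223 higher and 3764 lower. Because so many genes moved, these directions hold relative to the typical gene and say nothing about the amount of RNA per cell.

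**Figure D1:**
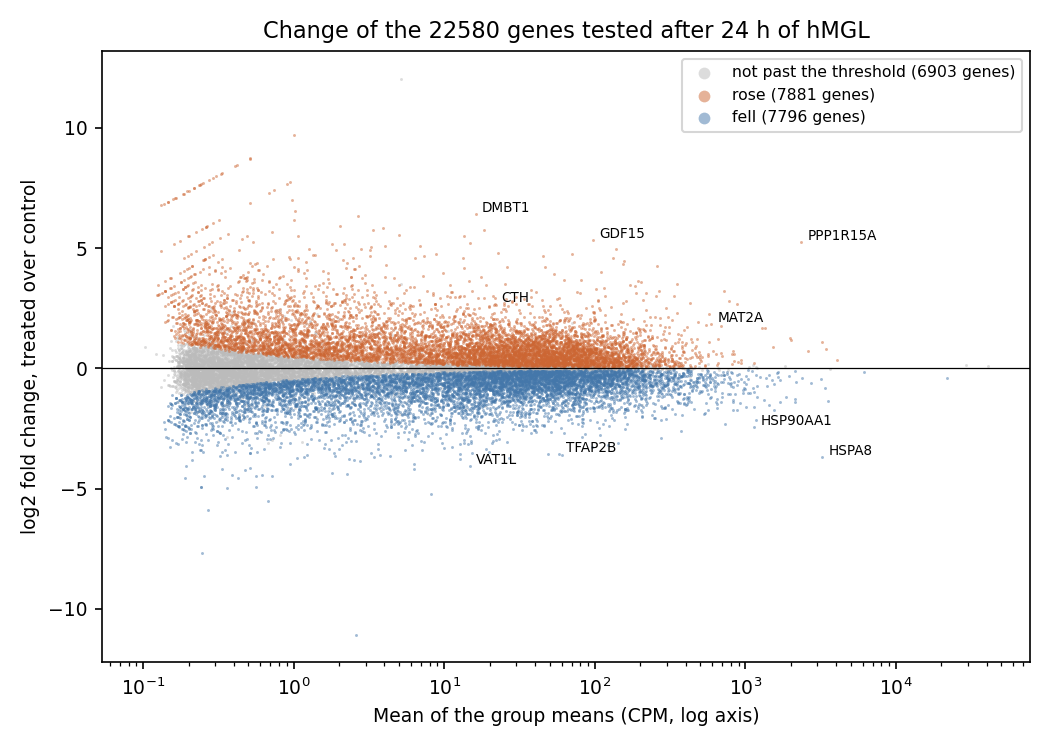
Log2 fold change of treated over control (vertical axis) against the mean of the group means in CPM (horizontal log axis) for the 22580 genes tested, with 7881 genes that rose in orange, 7796 that fell in blue and the others in grey. PPP1R15A and HSPA8 stand out among abundant genes, at log2 fold changes of 5.24 and −3.71.

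The 12 highest rises among genes with a mean of at least 10 CPM ran from GADD45B, at a log2 fold change of 4.47, to DMBT1, a secreted scavenger receptor family protein, at 6.42. DMBT1 rose from 0.374 ± 0.107 to 32.0 ± 4.64 CPM. The immediate early transcription factor EGR1 rose by a log2 fold change of 4.95 ± 0.085 (SE), and ATF3, a transcription factor of the stress response, by 4.76 ± 0.045. Others were TEX14 at 5.48, LURAP1L at 4.81, XDH at 4.66, TTN at 4.58 and DHRS2 at 4.57, together with GDF15 at 5.34 and PPP1R15A. PPP1R15A (ENSG00000087074) lies on chromosome 19 at 48872392 to 48876057 and had the lowest adjusted p of these genes, 4.16e-23 in edgeR. With an offset for effective transcript length the log2 fold change of TTN was 1.41 and that of TEX14 was 4.18.

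The 12 deepest falls ran from TP73, a member of the p53 family, at −3.28 to VAT1L at −4.06. HSPA8 (ENSG00000109971, chromosome 11 at 123057489 to 123063230) was the most abundant of them (adjusted p = 6.81e-21 in edgeR). CCNE2, cyclin E2 of the G1/S transition, fell from 36.5 ± 1.39 to 3.29 ± 0.279 CPM, a log2 fold change of −3.47. TFAP2B, a transcription factor of the neural crest, fell from 107.1 ± 7.36 to 9.09 ± 0.721 CPM, and MAP2K6, a kinase that activates p38, fell by 3.53 on the log2 scale. The other genes were GBP2 at −3.76, FAM20C at −3.73, DHRS3 at −3.59, ASB9 at −3.58, SAMD1 at −3.56 and DPYSL5 at −3.34. With an offset for effective transcript length the value of FAM20C was −2.97.

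In the list of ATF4 targets of the amino acid response, 31 of 34 tested members rose, 1 fell and 2 did not pass. The median log2 fold change was 1.75 (camera, higher, adjusted p = 4.91e-19, and adjusted p = 0.0334 with an estimated correlation). It was the only list of the 35 to pass with an estimated correlation. A call lost in that version does not by itself show a high correlation within the list. The NF-kB list had an estimated correlation of −0.038, under the preset 0.01, and its camera adjusted p still went from 0.000249 to 0.214. DDIT3, the transcription factor CHOP, rose from 12.9 ± 0.631 to 205.1 ± 5.07 CPM, 15.9-fold. CHAC1, which degrades glutathione, rose 15.4-fold, and TRIB3, a pseudokinase that inhibits ATF4, rose 8.15-fold. ASNS, asparagine synthetase, rose 1.64-fold and SLC7A11, the cystine transporter, rose 1.3-fold. The mRNA of ATF4 itself rose 1.51-fold, from 9.67 ± 1.63 to 14.6 ± 1.62 CPM (adjusted p = 0.00981 in edgeR), a level that leaves out any of its transcripts without a gene match. JDP2, which fell by 0.52 on the log2 scale, was the only member to fall, and it did not pass in limma on log2 TPM (adjusted p = 0.203 with 1 added and 0.214 with 0.1 added).

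**Figure D2:**
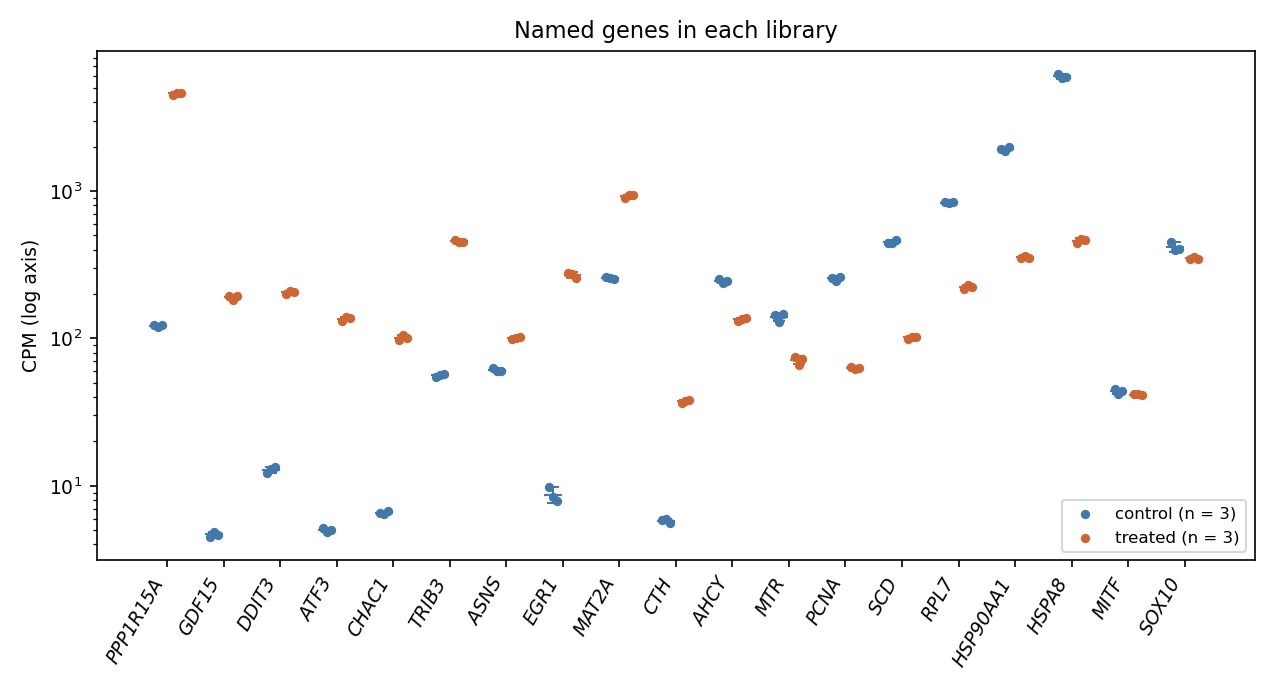
CPM (vertical log axis) of 19 named genes in each of the 3 control (blue) and 3 treated (orange) libraries, with a line at the mean and bars of 1 SD. PPP1R15A goes from 121.7 to 4586 CPM and HSPA8 from 5992 to 459.6 CPM, while MITF stays at 43.8 and 41.5 CPM.

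Enzymes that make and use methionine moved in opposite directions. MAT2A, which makes S-adenosylmethionine from methionine, rose from 257.4 ± 4.27 to 923.6 ± 20.7 CPM, 3.59-fold. CTH, which makes cysteine in transsulfuration, rose 6.44-fold from 5.81 ± 0.194 CPM. CBS, the first enzyme of transsulfuration, rose 1.12-fold from 26.4 ± 1.53 CPM. AHCY, which breaks down S-adenosylhomocysteine, fell by 0.86 on the log2 scale, methionine synthase MTR by 0.97, the methyltransferase PEMT by 1.52 and MTAP, the first enzyme of methionine salvage, by 0.75. In the whole list of the methionine cycle, salvage and transsulfuration, 9 of 24 members rose, 12 fell and 3 did not pass. Its median log2 fold change was −0.06 and its mean 0.04, with camera lower (adjusted p = 0.739) and fry higher (adjusted p = 0.0864), and the median turned to 0.01 with library totals alone and with limma on log2(TPM + 0.1). MTR had a log2 fold change of −0.31 in limma on log2(TPM + 1), and CBS did not pass there (adjusted p = 0.0557).

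Serine synthesis and folate metabolism were likewise split, with 10 of 23 members higher, 9 lower and 4 not passing. SHMT2, the mitochondrial serine hydroxymethyltransferase, rose 1.62-fold to 476.4 ± 8.33 CPM, and the mitochondrial folate genes MTHFD2L and SLC25A32 rose 2.93-fold and 1.73-fold. Cytosolic SHMT1 fell by 1.54 on the log2 scale and thymidylate synthase TYMS by 1.99. The median of this list was 0.19 but its mean was −0.08 and camera read it as lower (adjusted p = 0.762). The median was 0.07 with an offset for effective transcript length, 0.08 with the stricter filter, with limma on log2(TPM + 1) and without control replicate 1 or control replicate 2, and 0.32 without treated replicate 4. Of 14 tested genes of polyamine metabolism, 5 rose, 7 fell and 2 did not pass. SAT1, which acetylates spermidine and spermine for breakdown or export, rose 5.95-fold, ornithine decarboxylase ODC1 rose 3.21-fold, and spermine synthase SMS fell from 424.1 ± 13.0 to 136.2 ± 0.732 CPM. Its median was −0.09 while its mean was 0.11 and camera gave higher (adjusted p = 0.965), and the median was 0.02 with limma on log2 TPM and 0.06 with an offset for GC content and length. Camera turned to lower for polyamines without control replicate 1 (adjusted p = 0.942), control replicate 2 (0.806) or treated replicate 6 (0.929).

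Among the cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 10 of 20 rose, 6 fell and 4 did not pass (camera, higher, adjusted p = 0.484). SARS1 rose 2.67-fold, YARS1 1.96-fold and MARS1 1.81-fold, while QARS1 fell by 2.15 on the log2 scale. Of the 17 mitochondrial synthetases, 9 rose, 4 fell and 4 did not pass (camera, higher, adjusted p = 0.283). PARS2 rose 3.32-fold and MARS2 2.60-fold, and SARS2 fell by 1.57. Chaperones and degradation factors of the endoplasmic reticulum were also split, with 11 of 25 higher, 11 lower and 3 not passing. The stress sensor ERN1 rose 6.55-fold, its target XBP1 2.12-fold and HERPUD1 1.97-fold. The chaperones CALR and HSP90B1 fell by 1.01 and 0.62. The median of this list was −0.05, its mean was 0.16 and camera gave higher (adjusted p = 0.739), and the median turned positive with library totals (0.03), with limma on log2 TPM (0.08 with 1 added and 0.09 with 0.1 added) and without treated replicate 6 (0.02).

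For cholesterol synthesis and uptake, 20 of 24 tested members fell, 1 rose and 3 did not pass, and 21 fell and 2 rose adjusted over the list alone. The median log2 fold change was −0.84 (camera, lower, adjusted p = 1.11e-06, but adjusted p = 0.267 with an estimated correlation). SREBF2, the transcription factor that switches on cholesterol synthesis, fell from 64.3 ± 0.598 to 21.7 ± 0.683 CPM. ACAT2 fell by 2.31 on the log2 scale, and SC5D was the member that rose (0.59). For fatty acid synthesis and desaturation, 17 of 18 members fell and GPAM, which starts glycerolipid synthesis, rose 2.26-fold. The median was −1.21 (camera, lower, adjusted p = 2.72e-09, but adjusted p = 0.267 with an estimated correlation). The stearoyl-CoA desaturase SCD fell from 451.5 ± 12.5 to 101.4 ± 1.64 CPM, FADS1 by 2.22 on the log2 scale and SREBF1 by 1.84. In phosphatidylcholine synthesis 9 of 14 members fell, 2 rose and 3 did not pass (median −0.5, camera, lower, adjusted p = 0.00461, but adjusted p = 0.388 with an estimated correlation). The choline transporter SLC44A1 fell by 1.65, ETNK2 by 1.65 and PEMT by 1.52, and PISD rose 1.59-fold.

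Of 28 glutathione and NRF2 target genes, 15 fell, 11 rose and 2 did not pass. The median was −0.29 (camera, lower, adjusted p = 0.0396, but adjusted p = 0.641 with an estimated correlation), and it ran from −0.10 with limma on log2(TPM + 1) to −0.49 with the stricter filter. NQO1 fell from 536.2 ± 21.7 to 145.2 ± 4.91 CPM, and TKT and TALDO1 of the pentose phosphate pathway fell by 1.66 and 1.65. HMOX1, heme oxygenase, rose 3.83-fold and ferritin FTH1 rose 2.39-fold to 2791 ± 33.8 CPM. This call ended when any library except control replicate 3 was left out, with adjusted p = 0.0688 without control replicate 1, 0.0848 without control replicate 2, and 0.0666, 0.0556 and 0.0986 without treated replicates 4, 5 and 6. In the list of glycolysis and hypoxia genes, 22 of 31 fell, 8 rose and 1 did not pass (median −0.69, camera, lower, adjusted p = 0.000149, but adjusted p = 0.421 with an estimated correlation). GPI and PFKP, enzymes of upper glycolysis, fell by 1.61 and 1.74, and PGK1 fell from 592.0 ± 16.3 to 255.9 ± 2.92 CPM. The secreted peptide ADM rose 6.05-fold and the glucose transporter SLC2A3 rose 3.10-fold.

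In the list of DNA replication and the G1/S transition, 35 of 38 members fell, 2 rose and 1 did not pass. The median log2 fold change was −1.31 (camera, lower, adjusted p = 4.91e-19, but adjusted p = 0.267 with an estimated correlation). PCNA, the sliding clamp of the replication fork, fell from 255.3 ± 8.06 to 62.7 ± 0.976 CPM. MCM6 of the replicative helicase fell by 2.48 on the log2 scale and DNA ligase LIG1 by 2.18. The exceptions were GINS3, which rose 2.03-fold, and FEN1, which rose 1.3-fold. In mitosis and G2/M, 32 of 39 members fell, 3 rose and 4 did not pass, and 33 fell and 3 rose adjusted over the list alone (median −0.6, camera, lower, adjusted p = 1.58e-08, but adjusted p = 0.421 with an estimated correlation). Cyclin A2 (CCNA2) fell from 128.1 ± 4.37 to 46.2 ± 1.72 CPM and the kinesin KIF20A by 1.19 on the log2 scale, while CKAP2L rose 1.46-fold.

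Of 27 replication-dependent histone genes, 18 fell and 9 rose (median −0.34, camera, lower, adjusted p = 0.025, but adjusted p = 0.728 with an estimated correlation). H1-5 fell from 220.4 ± 6.0 to 68.8 ± 3.20 CPM and H4C1 by 2.76 on the log2 scale. H3C10 rose from 1.49 ± 0.173 to 13.8 ± 0.790 CPM, and H2AC6 rose 1.92-fold. These mRNAs lack a poly(A) tail, and the labels do not give the library preparation. Among cyclins D and CDK inhibitors, 7 of 13 fell, 4 rose and 2 did not pass (camera, lower, adjusted p = 0.399). Cyclin D1 (CCND1) rose from 399.0 ± 5.43 to 917.0 ± 8.87 CPM, whereas cyclin D3 (CCND3) fell by 1.94 on the log2 scale and the retinoblastoma gene RB1 by 1.73. The CDK inhibitor CDKN1A rose 1.63-fold, from 83.4 ± 1.67 to 135.9 ± 3.17 CPM, and its log2 fold change of 0.70 became 1.46 with an offset for effective transcript length.

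Of 27 tested p53 target genes, 19 rose, 7 fell and 1 did not pass (median 0.95, camera, higher, adjusted p = 0.000189, but adjusted p = 0.281 with an estimated correlation). GADD45A, a growth arrest gene, rose from 28.6 ± 0.847 to 312.9 ± 4.28 CPM, 10.9-fold, and PMAIP1, which encodes the BH3-only protein NOXA, rose 10.3-fold. The death receptor TNFRSF10B rose 2.85-fold. BAX, a pore-forming protein of apoptosis, fell by 1.20 on the log2 scale and CCNG1 by 1.04. In the BCL2 family, 9 of 16 members rose, 4 fell and 3 did not pass (median 0.47, camera, higher, adjusted p = 0.073). BCL2L1, which encodes the anti-apoptotic BCL-XL, rose 2.93-fold and BBC3, which encodes the pro-apoptotic PUMA, rose 2.77-fold. BID and BAD, of the pro-apoptotic side, fell by 1.49 and 1.08. This list passed with no filter on low counts (adjusted p = 0.01), with an offset for effective transcript length (0.0155) and without control replicate 3 (0.0186).

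For MAPK pathway output, 19 of 24 members rose, 4 fell and 1 did not pass. The median log2 fold change was 1.31 (camera, higher, adjusted p = 5.74e-08, but adjusted p = 0.276 with an estimated correlation). DUSP5, a phosphatase of ERK, rose 5.22-fold, IER3 4.05-fold and the AP-1 factor FOSL1 3.06-fold to 588.8 ± 12.4 CPM. The ETS factors ETV1, ETV4 and ETV5, which are ERK targets too, fell by 0.46, 0.41 and 0.57 on the log2 scale. Among NF-kB targets and cytokines, 16 of 23 rose, 4 fell and 3 did not pass (median 1.27, camera, higher, adjusted p = 0.000249, but adjusted p = 0.214 with an estimated correlation). The cytokine LIF rose from 32.6 ± 1.64 to 108.4 ± 0.713 CPM, RELB rose 3.31-fold, and CSF2 (GM-CSF) rose from 0.393 ± 0.0889 to 13.4 ± 0.423 CPM. TRAF1 fell by 1.49 and TNFAIP2 by 0.79.

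Of 32 tested genes of the interferon response and antigen presentation, 16 fell, 8 rose and 8 did not pass (median −0.32, camera, lower, adjusted p = 0.478). IFI44 fell by 1.85 on the log2 scale and the immunoproteasome subunit PSMB9 by 1.61, while the RNA sensor IFIH1 rose 3.51-fold. CD274, which encodes PD-L1, rose from 2.92 ± 0.440 to 12.4 ± 0.829 CPM, and its log2 fold change of 2.09 became 1.27 with an offset for effective transcript length.

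The melanocyte regulator MITF did not pass the threshold (43.8 ± 1.86 and 41.5 ± 0.400 CPM, log2 fold change −0.08, adjusted p = 0.0804 in edgeR). SOX10, a neural crest factor of melanoma cells, fell by 0.26 on the log2 scale (417.4 ± 31.4 and 349.7 ± 6.77 CPM), a call that ended with an offset for GC content and length (−0.05, adjusted p = 0.289). MITF passed, lower, with the stricter filter (adjusted p = 0.0284), with an offset for effective transcript length (0.0111), without control replicate 2 (0.0271) and with an offset for GC content and length (0.00458). In the list of melanocyte differentiation, 12 of 22 tested members rose, 7 fell and 3 did not pass. Its median was 0.48 and its mean 0.18, and camera read it as higher (adjusted p = 0.967) but fry as lower (adjusted p = 0.016). Camera too read it as lower with DESeq2 size factors (adjusted p = 0.992), with an offset for effective transcript length (0.542) and without control replicate 3 (0.543). With the stricter filter, which removes members with low counts, 8 members rose, 8 fell and the median was 0.06. CDK2 rose 1.81-fold and PAX3 1.48-fold, while the endothelin receptor EDNRB fell by 1.35 and S100A1 by 0.89. PMEL, a melanosome protein, rose from 0.556 ± 0.0505 to 2.05 ± 0.0987 CPM, and its annotated position on chromosome 12 overlaps that of CDK2. In the list of the dedifferentiated and invasive melanoma state, 13 of 27 rose, 12 fell and 2 did not pass (median 0.07, camera, higher, adjusted p = 0.739). The nerve growth factor receptor NGFR rose 2.99-fold, and vimentin (VIM) fell from 3034 ± 81.9 to 1261 ± 13.8 CPM.

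Genes of the RNA methylation machinery, whose enzymes use S-adenosylmethionine or read the mark, rose: 20 of 26 were higher, 5 were lower and 1 did not pass. The median was 0.94 (camera, higher, adjusted p = 2.41e-06, but adjusted p = 0.389 with an estimated correlation). TRMT61A, a methyltransferase of tRNA, rose from 35.9 ± 1.46 to 120.2 ± 2.42 CPM, the cap methyltransferase CMTR2 3.09-fold and the reader of N6-methyladenosine YTHDF2 2.51-fold. METTL3, the catalytic subunit that writes this mark, fell by 0.35 on the log2 scale and FBL by 0.93. METTL3 did not pass in limma on log2 TPM (adjusted p = 0.208 with 1 added and 0.211 with 0.1 added). Among DNA and histone methyltransferases, 18 of 34 fell, 9 rose and 7 did not pass, and 19 fell and 9 rose adjusted over the list alone (median −0.23, camera, lower, adjusted p = 0.148). EHMT2, which methylates histone H3 lysine 9, fell by 1.65, the arginine methyltransferase PRMT1 fell from 259.0 ± 5.01 to 117.6 ± 3.95 CPM, and KMT5B rose 2.67-fold. Among histone and DNA demethylases, 12 of 20 rose, 6 fell and 2 did not pass, and 13 rose and 6 fell adjusted over the list alone (median 0.4, camera, higher, adjusted p = 0.0475, but adjusted p = 0.671 with an estimated correlation). KDM7A rose 2.90-fold, KDM6B 2.73-fold and TET3 1.92-fold, while KDM4B fell by 1.20 on the log2 scale. The call of the demethylases ended with an offset for effective transcript length (adjusted p = 0.13) and without control replicate 2 (0.0712), control replicate 3 (0.0558) or treated replicate 6 (0.0545). KDM4B stood at −0.56 with that offset and did not pass in limma on log2 TPM (adjusted p = 0.0629 with 1 added and 0.0511 with 0.1 added).

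All 53 cytosolic ribosomal protein genes of the list fell. The median log2 fold change was −0.57 (camera, lower, adjusted p = 8.31e-19, but adjusted p = 0.389 with an estimated correlation, which was 0.631). RPL7 fell from 834.5 ± 10.5 to 223.4 ± 6.60 CPM, RPL3 by 1.72 on the log2 scale and RPL13A by 1.59. With limma on log2 TPM 43 of the 53 passed with 1 added and 44 with 0.1 added, and none rose. Genes of ribosome biogenesis went the other way more often, with 24 of 35 higher, 8 lower and 3 not passing, and 25 higher and 8 lower adjusted over the list alone (median 0.17, camera, higher, adjusted p = 0.00535, but adjusted p = 0.71 with an estimated correlation). RRS1 rose 2.57-fold, PNO1 2.48-fold and RRN3, an initiation factor of RNA polymerase I, 2.39-fold. Nucleophosmin NPM1 fell from 3086 ± 53.5 to 1186 ± 25.7 CPM.

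Genes of the heat shock response fell: 16 of 18 were lower and 2 higher. The median was −1.4 (camera, lower, adjusted p = 3.4e-10, but adjusted p = 0.276 with an estimated correlation). Besides HSPA8, HSP90AA1 fell from 1926 ± 61.0 to 354.9 ± 6.61 CPM and its partner DNAJA1 from 395.6 ± 6.89 to 94.5 ± 1.8 CPM. DNAJB1 rose 1.35-fold and HSPB8 1.42-fold. Among genes of lysosomes and autophagy, 16 of 35 rose, 13 fell and 6 did not pass, and 17 rose and 13 fell adjusted over the list alone (median 0.24, camera, higher, adjusted p = 0.173). MAP1LC3B, which encodes the autophagosome protein LC3B, rose 5.93-fold to 220.5 ± 3.38 CPM, FLCN 3.05-fold and ATG12 2.52-fold, and the lysosomal enzyme GLA fell by 1.52 on the log2 scale. The list passed with no filter on low counts (adjusted p = 0.0477).

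**Figure D3:**
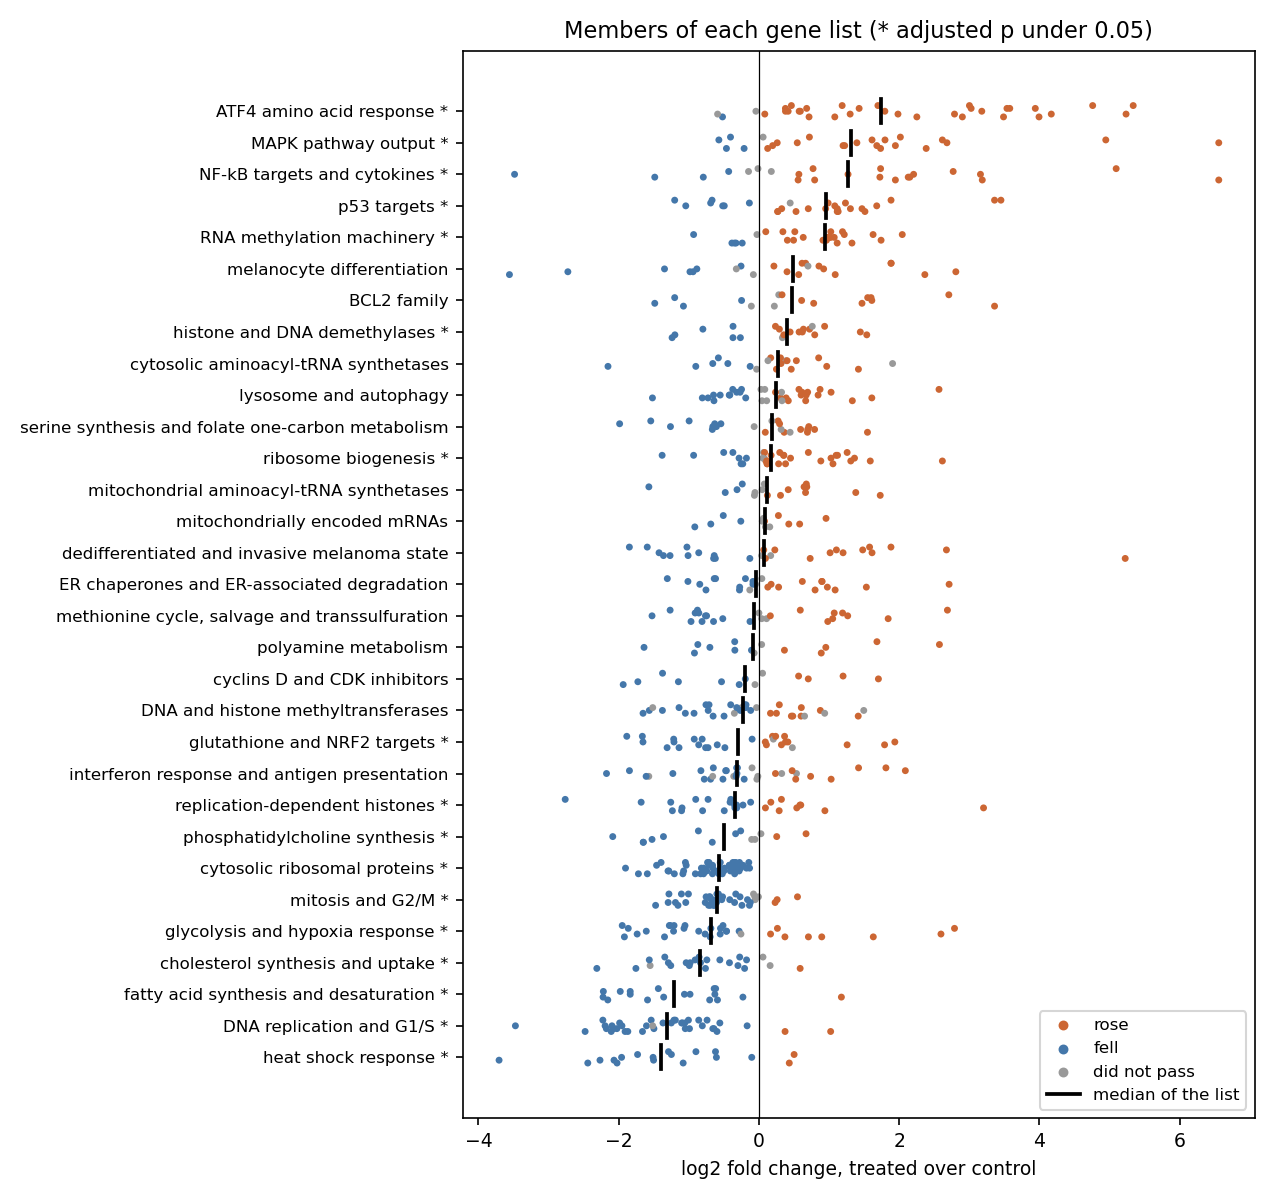
Log2 fold change of treated over control (horizontal axis) of the tested members of 31 gene lists, with a point per gene (orange, rose; blue, fell; grey, did not pass) and a black bar at the median of the list. The ATF4 amino acid response has the highest median, 1.75, and the heat shock response the lowest, −1.4. Stars mark lists past the threshold with the preset correlation.

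Over the 35 lists, 732 of 821 tested members passed the threshold. With the preset correlation camera called 17 lists, 7 higher and 10 lower, while fry called 33 and camera with an estimated correlation called 1.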

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

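Of the tests in this part, the offset for GC content and transcript length was chosen after seeing the data, and the values of the HSPA8 isoforms were looked up after the result was seen. The fall of HSPA8 and the heat shock genes was itself picked from the results, and its tests were set up for that pattern.

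Transcripts without a gene match stand outside the comparison of genes, and they carried a difference between the groups. Of 12333 such transcripts with enough counts, 1775 (14.4%) passed the threshold in edgeR, with 1057 higher and 718 lower in treated cells. They were not assigned to genes here and are given as counts alone.

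The number of genes that changed, 15677 of 22580, was weighed against chance, base composition and gene structure. Splitting the 6 libraries into 3 and 3 gives 10 splits, which is too few for a share under 0.05. The real split was the 1 split with as many genes, and the highest count of the others was 0 in edgeR (124 to 170 genes at an unadjusted p under 0.05). Each of the others mixes treated and control libraries in both groups, so the difference between the groups enters their spread and keeps their counts low. These splits therefore do not decide on chance. A trend with GC content and length is argued against as the whole cause, since 94.8% of the genes called were still called in the same direction with the offset. Exon number may account for a part of the count. The median log2 fold change of single-exon genes exceeded that of genes with 5 or more exons, matched on mean expression, by 0.27. The 95% interval of this difference, 0.108 to 0.408, came from resampling genes and holds no spread between cultures. Yet among genes with 10 or more exons 32.9% rose and 47.6% fell, and the treatment itself stays open as a biological cause.

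The fall of HSPA8 and the heat shock response genes was weighed against a general fall of abundant genes and against reads given to other transcripts. The median of the list, −1.396, lay below all of 10000 random lists matched on mean expression (lowest −0.897, median −0.146). The list thus fell more than genes of like abundance, which argues against a fall of abundant genes in general. Its rank among the random lists is no measure of chance, because the list was taken up for its fall. The random lists also hold no correlation between genes, estimated at 0.361 for this list. The 17 processed pseudogenes named after HSPA8 went from 0.93 to 0.72 CPM in sum, a change of −0.0038% of the CPM that HSPA8 lost, so they did not take up its reads. A move of reads to transcripts without a gene match cannot be told apart from a loss of HSPA8 mRNA: the changes of such transcripts summed to 14458 CPM for those higher and −15346 CPM for those lower (net −888 CPM), sums over transcripts not assigned to genes, which do not decide where the 5533 CPM of HSPA8 went, the highest gain of a single transcript was 397.2 CPM, and the isoforms HSPA8-224 and HSPA8-221 went from at least 4278 and 1172 CPM in controls to at most 339.2 and 92.4 CPM in treated libraries. As a share of all counts, transcripts without a gene match took 4.86% to 5.01% in control libraries and 5.05% to 5.13% in treated libraries. The sign of their net change therefore depends on the scaling. A response to methionine loss under hMGL stays open as a biological explanation that these data did not test separately.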

How the results depend on the processing

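The alternatives restricted to protein-coding genes, with an offset for GC content and length, and without the 7SL, 7SK, RMRP and RPPH1 genes were chosen after seeing the data. The count of changed genes stayed between 12201 (protein-coding genes alone) and 17011 (no filter) under every alternative except a minimum fold change of 1.5, which by its construction gave 7987 (4223 higher and 3764 lower). Leaving out a replicate gave 15050 to 15335. DESeq2 kept 86.7% of the calls in the same direction, limma on log2(TPM + 1) 80%, with 22 reversed, and the offset for effective transcript length 89.9%, with 34 reversed. Among lists called by camera, the median moved by over 1.5 times with limma on log2(TPM + 1) for phosphatidylcholine (−0.29), glycolysis (−0.45) and ribosome biogenesis (0.31), and for glutathione. No scaling moved the median of all genes by more than 0.096. Of the comparisons of named genes, 4382 kept the side of the threshold, 74 lost the call, 4 gained it and 3 changed direction with a call before or after. For lists these counts were 340, 25, 19 and 1. Comparisons that passed in neither setting count as kept even where the direction turned. The methionine list, lower by camera in the main test, was higher with an offset for effective transcript length and passed in neither. KRT18, at −0.08, turned to 0.017 with limma on log2 TPM, where it did not pass (adjusted p = 0.863 with 1 added and 0.866 with 0.1 added). With the offset for GC content and length it reversed to 0.102, and it lost its call in several other settings. Adding 1 to TPM shrinks the folds of genes at low TPM by construction, as for DMBT1 (1.90), PMEL (0.74) and CCL2 (−0.74).

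With an estimated correlation the adjusted p of the lists called before was 0.267 for cholesterol, fatty acids and DNA replication, 0.388 for phosphatidylcholine, 0.641 for glutathione, 0.421 for mitosis and glycolysis, 0.728 for histones, 0.281 for p53, 0.276 for MAPK and heat shock, 0.214 for NF-kB, 0.671 for demethylases, 0.389 for RNA methylation and ribosomal proteins, and 0.71 for ribosome biogenesis. Fry, which does not compare a list with other genes, gave an adjusted p of 0.00952 for serine and folate, 0.00407 for polyamines and interferon, 0.0062 and 0.00217 for cytosolic and mitochondrial tRNA synthetases, 0.0151 for the endoplasmic reticulum, 0.000377 for cyclins D, 2.99e-05 for the BCL2 family, 0.00295 for the dedifferentiated state, 0.000213 for methyltransferases, 0.000149 for lysosomes, 0.0039 for metallothioneins, 0.0298, 0.00252 and 0.00135 for blood, keratinocyte and fibroblast markers, and 0.016, reversed to lower, for melanocyte differentiation. No filter on low counts gave 0.01 for the BCL2 family and 0.0477 for lysosomes, and the offset for effective transcript length 0.0155 for the BCL2 family and 0.13 for demethylases. Leaving out a replicate gave 0.00574 to 0.0986 for glutathione, 0.0295 to 0.0712 for demethylases and 0.0186 to 0.115 for the BCL2 family. Where no reason is given, the cause was not tested. Depth limits genes under about 1 CPM, which the stricter filter removes.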

Other observations

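The test on nuclear RNAs in this part was chosen after the result was seen, and the other test was written down before.

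Mitochondrially encoded mRNAs went both ways: 5 of 13 rose, 4 fell and 4 did not pass (median log2 fold change 0.08, camera, higher, adjusted p = 0.794, fry adjusted p = 0.152). MT-ND2, a subunit of respiratory complex I, rose 1.94-fold from 108.5 ± 2.47 to 210.7 ± 2.65 CPM (SD, n = 3) and MT-ND3 rose 1.5-fold. MT-ND6 fell by 0.91 on the log2 scale and MT-CO2, a subunit of cytochrome oxidase, by 0.69. Mitochondrial rRNA took 0.0455% to 0.0602% of the counts in control libraries and 0.0759% to 0.0815% in treated libraries, and nuclear rRNA 0.0333% to 0.0431% and 0.0181% to 0.0210%. Only 2 of 8 metallothionein genes had enough counts to test, and both rose: MT1X from 9.83 ± 0.383 to 13.5 ± 0.0824 CPM and MT2A from 207.7 ± 16.9 to 260.8 ± 21.9 CPM (camera, higher, adjusted p = 0.484). MT2A did not pass without control replicate 2 (adjusted p = 0.108), control replicate 3 (0.0792), treated replicate 5 (0.072) or treated replicate 6 (0.0731).

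Markers of other cell types were near the floor or mixed in direction. Of 13 blood and immune genes 4 were tested, of which 3 rose and 1 fell (median 0.88, camera, higher, adjusted p = 0.804). Camera turned to lower with no filter on low counts (adjusted p = 0.97) and without control replicate 1 (0.956), treated replicate 5 (0.873) or treated replicate 6 (0.916). The myeloid genes ITGAM and CSF1R reached 0.534 ± 0.104 and 1.45 ± 0.295 CPM in treated cells, CD14 reached 0.415 ± 0.0838 CPM, and lysozyme LYZ fell from 6.99 ± 0.654 to 2.19 ± 0.334 CPM. ITGAM stood at 0.0121 CPM in the controls, so its fold depends on the count added. CD14 did not pass in DESeq2 (adjusted p = 0.192) or when single libraries were left out, with adjusted p = 0.198 without control replicate 1, 0.064 without control replicate 2, and 0.0757, 0.0654 and 0.165 without treated replicates 4, 5 and 6. Of 10 tested keratinocyte and epithelial genes 6 rose, 2 fell and 2 did not pass (median 0.64, camera, higher, adjusted p = 0.478). KRT10 rose 1.78-fold to 53 ± 0.863 CPM, KRT5 rose to 0.566 ± 0.0744 CPM, and KRT14 fell by 0.87 on the log2 scale. With the stricter filter, which removes genes near the floor, the medians of the blood and of the keratinocyte list became −0.45 and −0.06, and that of the fibroblast and endothelial list −0.7. Of 11 tested fibroblast and endothelial genes 4 fell, 2 rose and 5 did not pass (median −0.15, or −0.57 with an offset for effective transcript length, camera, lower, adjusted p = 0.484). PDGFRB fell from 9.65 ± 1.03 to 2.08 ± 0.167 CPM, and THY1 rose from 0.344 ± 0.206 to 2.06 ± 0.14 CPM.

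The share of counts in transcripts annotated as retained intron was 4.54 ± 0.132% in controls and 4.0 ± 0.1% in treated cells (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). With the same exact permutation p = 0.1 each, the shares of processed transcripts (2.88% to 3.16%), transcripts subject to nonsense-mediated decay (3.67% to 4.02%) and lincRNA (1.01% to 1.19%) were higher in treated cells, and those of processed pseudogenes (0.334% to 0.246%) and antisense transcripts (0.680% to 0.629%) lower. The retained-intron share was 4.41% to 4.68% in control libraries and 3.90% to 4.10% in treated libraries. For transcripts so annotated, this argues against a general rise of unspliced RNA. Whether nuclear RNA rose in general stays open. The median log2 fold change of 6 nuclear RNAs was −0.457, with 5 lower (from RMRP at −0.16 to TUG1 at −0.99) and MALAT1 higher at 0.36, all past the threshold in edgeR. The 95% interval of this median, −0.967 to 0.101, reaches above 0 and came from resampling the 6 RNAs, not cultures. Another hypothesis was that retained-intron transcripts had gained against coding transcripts of the same genes. Over 4701 genes the median change of that log2 ratio was −0.052, with 46.4% of genes higher. The 95% interval, −0.07 to −0.03, came from resampling genes and holds no spread between cultures. The medians of the libraries ran from −3.396 to −3.271 in controls and from −3.465 to −3.353 in treated cells. This overlap argues against a gain shared by all treated libraries.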
